A study of Danio rerio with 2 samples.

How the data were processed

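The series compared RNA from whole zebrafish embryos of the AB strain at 6 hpf, either mock-injected or injected with Dcp2-DN. Per the labels' protocols, total RNA came from pools of 40 to 50 embryos, was treated with DNase and column-purified, and was made into stranded libraries after removal of ribosomal RNA, so transcripts without a poly(A) tail were also captured. Each group had 1 sample entry, and the design text names 3 replicates per group. Grouping followed the sample labels.

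The data were a single comparison table with the header of a Cuffdiff gene-level output. The submitters' processing notes name TopHat 1.4.0 and Cuffdiff 2.1.1 and the builds Zv9 and danRer7 (names of the same assembly). The annotation release, the scaling between libraries and whether counting used strand were not given in the sources used here. Per the file headers, the authors deposited 1 FPKM value per gene and group. Cuffdiff estimates such a value over all libraries it is given for a group. How many libraries entered here was not given in the sources used. The p-value and q-value of each gene are the authors' deposited Cuffdiff results, and per the file headers each row also carries a test status and a call. The call equalled a status of OK with a q-value under 0.05 in all 32571 rows. The group names within the rows read mockB and DCP2 throughout, and these were taken as mock and Dcp2-DN from the sample titles. Values per library were not analysed here, so no error per group, no count-based model, no test of replicate blocks and no test leaving out a replicate could be run. Library depth is unknown, which leaves the precision of each FPKM value to the authors' own test.

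The table had passed through a spreadsheet program. Its log2 fold change and test statistic columns held cells that were not numbers and were not used. Log2 ratios were recomputed as log2((Dcp2-DN FPKM + 0.1)/(mock FPKM + 0.1)), which understates the change of low genes. Folds in the text are ratios of the FPKM values without a pseudocount. Gene names turned into dates stood in 18 rows, of which 13 were restored through their gene ID. Of the 32571 gene IDs, 20899 were present in the name table used here. Names and IDs otherwise stand as in the deposited table. Small structural RNAs were recognised by name in 4001 rows and kept. A further 504 rows had no symbol. Coordinates are those of the deposited table on Zv9, and whether starts count from 0 or 1 was not given. They are locus spans, and 482 called genes shared theirs with another gene. Genes that share a locus or have near-identical copies are therefore uncertain.

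Of the 32571 rows, 14810 had a test by the authors. The other 17761 were listed as NOTEST (17651), LOWDATA (109) or FAIL (1) and entered no count of calls. Both groups were at 0 in 7364 rows. At an unadjusted p under 0.05 the authors' deposited table held 5284 genes, and its lowest p was 5e-05, which 1249 rows shared. The summed FPKM was 963061 in mock and 908503 in Dcp2-DN embryos.

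The lists, tests and the rule for named genes were fixed before the data were examined. There were 19 gene lists for maternal, germ cell, decay, germ layer, extraembryonic, stress, metabolic and reference genes, and lists could share members. For each list the median log2 ratio over genes with a mean of at least 1 FPKM, minus the median of all such genes (0.12), was placed among 10000 random lists of the same size matched on mean FPKM in 10 bins. This percentile describes the deposited values and is no test of the conditions. The numbers of list members called higher and lower in the authors' deposited table were compared with all other tested genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 38 tests (19 lists, both directions). Genes are not independent replicates, so these tests describe how calls are spread over genes. The count adjusted over the list alone applies Benjamini-Hochberg to the authors' p-values of the tested members.

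Named genes were dcp2, the 8 largest rises and 8 largest falls by log2 ratio among called genes with a symbol and at least 10 FPKM in the higher group, up to 2 rises and 2 falls per list among called members, and the 3 most abundant called genes in each direction. List members without a call were named as values only. Some items that this rule or these lists take are not reported here. A few further genes (bmp4, krt5, krt8, krt17, ppl, anxa1b, hsp90aa1.2, hsp90ab1, hspb1, brd2b, gapdh, rnf11b and btg2) and those of the closing section were named after their values were seen, as were the examples without a call.

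Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9. The list statistics were tested on simulated data for this comparison, with 100 trials per setting and lists of 25 genes. With no shift planted among 15457 genes, 7 of 100 list medians fell outside the middle 95% of random lists. With log2 shifts of 0.25 and 0.5, 44 and 98 of 100 did. Fisher's exact test among 14810 genes passed in 5 of 100 trials with no enrichment and in 75 of 100 at odds of 3. The simulated ratios were independent and unrelated to expression, members were drawn at random, and fewer random lists were used per trial. These trials therefore do not check the matching on expression. The exact test trials used the share of genes called higher (20.6%), so they do not cover falls (4.35%).

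Alternatives covered the pseudocount (1 FPKM, or none), the filter on low values (none, or a mean of at least 10 FPKM), the q threshold (0.01), fold minimums (1.5 for list calls, 2 for all calls) and the centring. Leaving out structural RNAs, leaving out members of another list, and random lists matched on expression for the calls of lists and symbol stems were alternatives chosen after seeing the data. A planned relation of log2 ratios to transcript features, such as 3' UTR length and sequence, was left out because no transcript sequences were used here.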

Results

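RNA from whole zebrafish embryos of the AB strain was measured at 6 hpf (hours post fertilization), the start of gastrulation, in a mock-injected group and in a group injected with Dcp2-DN. Dcp2 is the catalytic subunit of the decapping complex, which removes the cap of an mRNA ahead of its decay from that end. Dcp2-DN is used in this field as a dominant-negative form, and the series title describes the experiment as Dcp2 inhibition. The question behind the comparison was which transcripts of the early embryo change in level when Dcp2 is inhibited, at a stage when many maternal mRNAs are being cleared. Each group had 1 sample entry, and the design text states that 3 replicates were made. The authors' deposited table held 1 FPKM value per gene and group, so values below carry no SD and no n. FPKM is fragments per kilobase of transcript, scaled to the number of fragments mapped. The spread between replicates could enter only through the authors' own Cuffdiff test. Whether all 3 replicates entered that test was not given, so its p-values may not measure the spread between replicates. Where they do, that spread may be technical. Depth was unknown, since the table held no counts. Genes are described as called where the authors' deposited table marked them significant, which was the case for tested rows with a q-value under 0.05.

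The symbol dcp2 was carried by 2 gene models, neither of which was called in the authors' deposited table. ENSDARG00000039016 (chromosome 10, 8458720 to 8479699, Zv9 coordinates as the authors' files give them) was at 13.9 FPKM in mock and 16.7 FPKM in Dcp2-DN embryos, 1.2 times the mock value. In the authors' deposited table this model had p = 0.03545 and q = 0.109 and was not called. ENSDARG00000089419 (chromosome 10, 8616815 to 8636669) was at 0.0398 FPKM in mock and 212 FPKM in Dcp2-DN embryos, a log2 ratio of 10.56 with a pseudocount of 0.1 FPKM. The authors' deposited table gave p = 0.147 and q = 0.303 for it, so this difference was also not called despite its size. The higher value stood in the group that the labels describe as injected with Dcp2-DN.

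Most of the called differences were rises in Dcp2-DN embryos. Of 14810 genes with a test in the authors' deposited table, 3051 (20.6%) were called higher and 644 (4.35%) were called lower. Rises were also the larger changes. In the authors' deposited table the median fold of the genes called higher was 1.56, and that of the genes called lower was 1.31 in the downward direction. At least 2-fold differences were found for 470 genes called higher and 27 called lower in the authors' deposited table. Over the 15457 rows with a mean of at least 1 FPKM, the median log2 ratio of Dcp2-DN over mock was 0.12, or 1.08-fold, with 2360 rows above 1.5-fold higher and 449 beyond 1.5-fold lower.

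**Figure D1:**
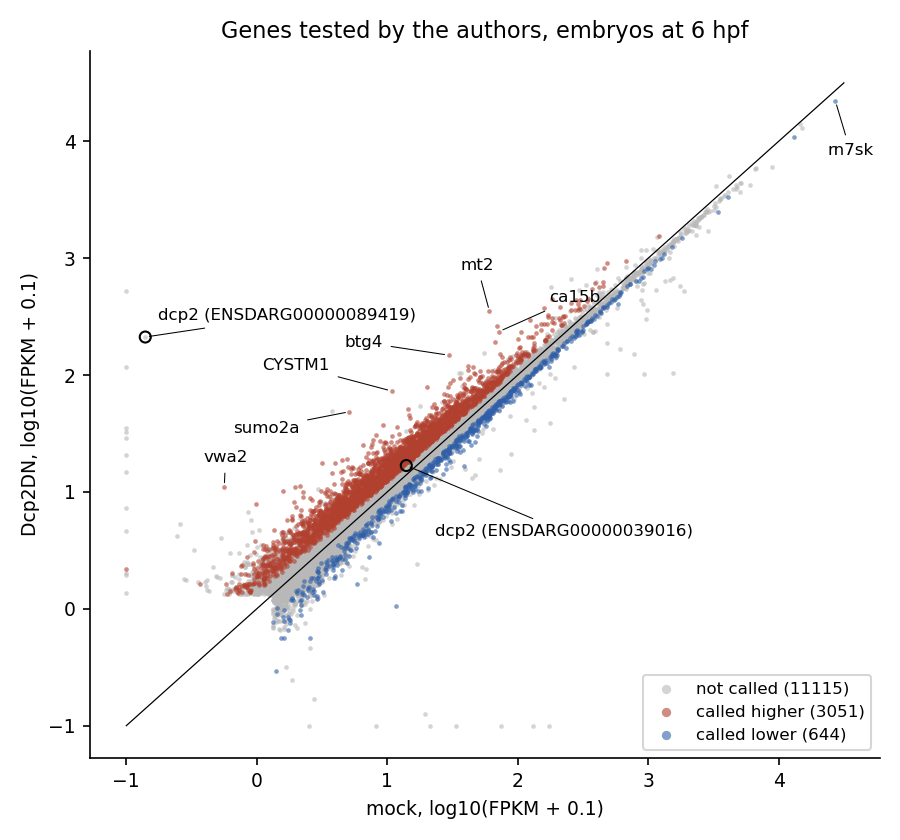
FPKM in mock (x axis) and Dcp2-DN embryos (y axis), both as log10(FPKM + 0.1), 1 point per gene tested by the authors, with the line of equal values. Red points (3051) were called higher and blue points (644) called lower in the authors' deposited table, grey points were not called, and open circles mark both dcp2 gene models.

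The gene with the largest called rise was vwa2 (ENSDARG00000075441, chromosome 12, 31888089 to 31914534), which encodes a protein with von Willebrand factor A domains, from 0.464 to 10.97 FPKM or 23.7-fold. Next were sumo2a, a small ubiquitin-like modifier gene, from 5.04 to 48.5 FPKM (9.63-fold), CYSTM1 from 10.7 to 72.9 FPKM (6.81-fold), and hbegfa, a ligand of the EGF receptor, from 1.49 to 10.03 FPKM (6.74-fold). The metallothionein gene mt2, whose product binds metal ions, rose from 60.6 to 351 FPKM (5.78-fold). mbnl1, a muscleblind splicing regulator, rose from 1.87 to 10.8 FPKM (5.78-fold). btg4 (ENSDARG00000035171, chromosome 5, 59273721 to 59275804), which encodes an adaptor of the CCR4-NOT deadenylase in oocytes and eggs, rose from 29.5 to 148 FPKM (5.02-fold), and COBLL1 (2 of 2) from 9.22 to 37.1 FPKM (4.03-fold). Their q-values in the authors' deposited table lay between 0.000593 and 0.0140, where 0.000593 was the lowest q in the table and was shared by 1249 rows. Among abundant genes, the cyclin B gene ccnb1 rose from 1219 to 1549.9 FPKM (1.27-fold), the BMP target id1 from 674 to 951 FPKM (1.41-fold) and the acid phosphatase gene acp5a from 486 to 915 FPKM (1.88-fold), each called in the authors' deposited table.

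The falls named here were smaller. The U3 small nucleolar RNA ENSDARG00000088747 fell from 38.4 to 16.6 FPKM (2.32-fold lower), with q = 0.0443 in the authors' deposited table. Several of the next genes encode transcription regulators of the gastrula. The LIM homeobox gene lhx5 fell from 20.5 to 10.6 FPKM (1.93-fold lower), the Brachyury-related gene ntlb from 10.6 to 5.50 FPKM (1.93-fold lower), the hairy-related gene her3 from 26.6 to 14.1 FPKM (1.89-fold lower) and prdm14 from 17.9 to 10.04 FPKM (1.78-fold lower). greb1l went from 12.8 to 6.80 FPKM (1.89-fold lower), and p4ha2, a subunit of the collagen prolyl hydroxylase, from 28 to 15.5 FPKM (1.81-fold lower). All of these except U3 had the lowest q, 0.000593, in the authors' deposited table. The locus of ntlb was shared with 1 other gene and that of greb1l with 2, and the authors' counting could split reads between genes of a shared locus. The most abundant genes called lower in the authors' deposited table were the structural RNAs rn7sk (27214 to 22170 FPKM, 1.23-fold lower) and Metazoa_SRP (13046 to 10895 FPKM, 1.2-fold lower) and the histone gene HIST1H4A (4072 to 3339 FPKM, 1.22-fold lower).

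The balance of rises and falls followed the expression level. Genes with a mean of 5 to 10 FPKM had the highest median log2 ratio, 0.22, and those of 500 FPKM or more the lowest, -0.18. Of the genes tested in the authors' deposited table, 29.3% of those at 10 to 20 FPKM were called higher and 3.11% lower. At 500 FPKM or more the authors' deposited table called 2.47% higher and 9.89% lower. The random lists behind the percentiles below were matched on mean expression, whereas Fisher's exact tests of calls compare a list with all other tested genes.

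**Figure D2:**
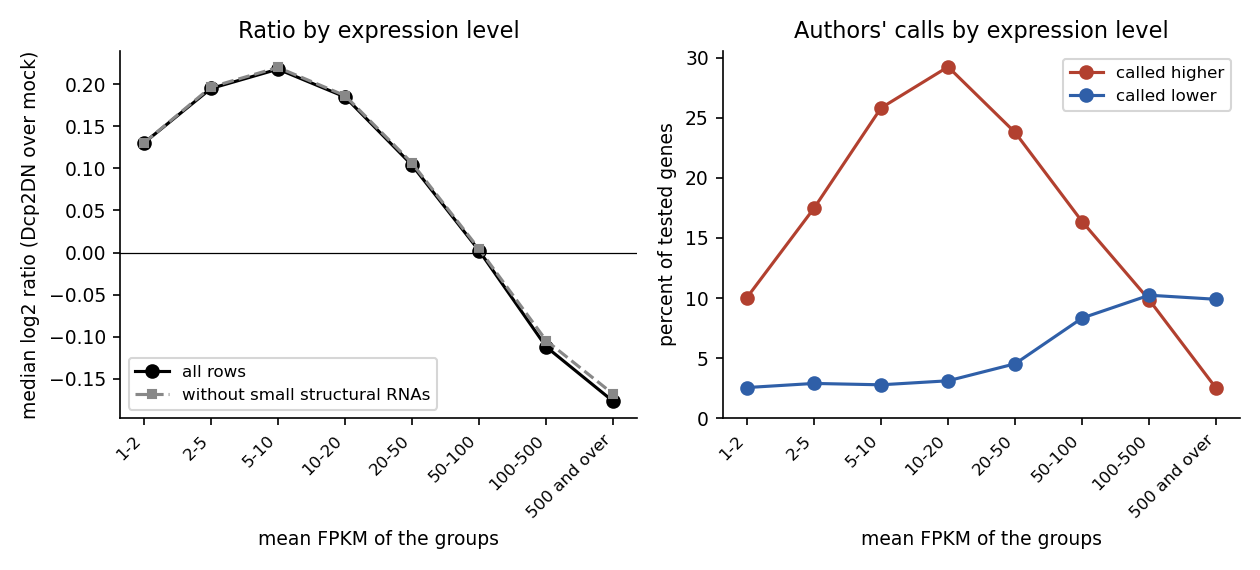
Median log2 ratio of Dcp2-DN over mock (left, y axis) and percent of tested genes called by the authors (right, y axis) in bins of mean FPKM (x axis). The median falls from 0.22 at 5 to 10 FPKM to -0.18 at 500 FPKM or more, and leaving out small structural RNAs (dashed grey) gives nearly the same line.

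Genes of the oocyte and egg were higher in Dcp2-DN embryos as a list, though not all of its members rose. Of the 47 tested oocyte and egg maternal genes, 25 were called higher and 0 lower in the authors' deposited table (26 and 1 when adjusted over the list alone, and 26 and 1 at an unadjusted p under 0.05). btg4 led this list, followed by ca15b, a carbonic anhydrase gene of the germ plasm, from 71.9 to 236 FPKM (3.28-fold). The share of calls higher exceeded that of all other tested genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 38 list tests, p = 8.02e-06). The list's median log2 ratio, minus that of all genes, was 0.27, at percentile 100 of 10000 random lists. Members without a call included zp3b, a zona pellucida gene, at 22.7 FPKM in mock and 22.8 FPKM in Dcp2-DN embryos, and pou5f1, a maternal pluripotency factor, at 888 and 793 FPKM. Of 13 tested genes with the symbol stem zp, a grouping made after the data were seen, 0 were called higher and 0 lower. Their lack of rises did not pass (Fisher's exact test, adjusted p = 0.559 over 438 stem tests).

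Germ plasm and germ cell genes moved in the same direction, with 15 of 27 called higher and 1 lower in the authors' deposited table (16 and 1 when adjusted over the list alone). Besides ca15b, pld6, a phospholipase of the piRNA pathway, rose from 1.52 to 3.64 FPKM (2.39-fold), while the tudor domain gene tdrd9 fell from 13.5 to 10.9 FPKM (1.24-fold lower). The list's median was 0.27 above that of all genes (percentile 99.6), and the excess of rises had an adjusted p = 0.000428 by Fisher's exact test (log2 odds 2.26). With a fold minimum of 1.5 on each call, it no longer passed this exact test (log2 odds 1.69, adjusted p = 0.0693). This list shares 10 rows with other lists.

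Transcripts known as targets of miR-430, the microRNA family that clears maternal mRNAs, held the largest share of rises among the 19 lists. Of 10 tested, 8 were called higher and 1 lower in the authors' deposited table (9 and 1 when adjusted over the list alone). The tetraspanin gene cd82b rose from 30.4 to 85.6 FPKM (2.82-fold) and dazl, an RNA-binding germ cell gene, from 23.6 to 51.8 FPKM (2.2-fold), whereas the Nodal antagonist lft1 fell from 41.4 to 32.3 FPKM (1.28-fold lower). The list's median was 0.47 above that of all genes, at percentile 99.99 of random lists, and Fisher's exact test for rises gave an adjusted p = 0.000526. Of the list's 12 rows, 8 also belong to another list.

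Among genes of the mRNA decay machinery, 22 of 70 were called higher and 2 lower in the authors' deposited table (23 and 2 when adjusted over the list alone). Rises were led by btg4 and by zfp36l2, an AU-rich element binding protein, from 16.8 to 39.7 FPKM (2.36-fold). The nonsense-mediated decay genes upf2 (32.1 to 26.1 FPKM, 1.23-fold lower) and smg1 (35.7 to 29.9 FPKM, 1.2-fold lower) fell. The exonuclease gene xrn1, which degrades decapped mRNA, was not called, at 49.9 and 42.8 FPKM. The excess of rises did not pass the test (Fisher's exact test, adjusted p = 0.0991), although at q under 0.01 it did (adjusted p = 0.00988). The median was 0.01 above that of all genes (percentile 95.3).

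Genes of the germ layers went both ways. Of 52 mesoderm and dorsal organizer genes, 13 were called higher and 11 lower in the authors' deposited table (15 and 11 when adjusted over the list alone). The Nodal antagonist lft2 rose from 50.8 to 88.0 FPKM (1.73-fold) and the notochord gene flh from 138 to 228 FPKM (1.65-fold), while ntlb and otx2, a homeobox gene of the anterior embryo, fell, the latter from 2.08 to 0.794 FPKM (2.62-fold lower). The share of falls exceeded that of all other tested genes (Fisher's exact test, adjusted p = 8.69e-05), and that of rises did not differ detectably (adjusted p = 0.578). The median lay at percentile 68.4 of random lists.

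The neural ectoderm list had the same form, with 6 of 24 called higher and 6 lower in the authors' deposited table (6 and 8 when adjusted over the list alone). The hairy-related genes her5 (30.1 to 65.7 FPKM, 2.18-fold) and her11 (11.6 to 18.3 FPKM, 1.58-fold), both of the midbrain-hindbrain region, rose. The Delta ligand gene dla fell from 1.69 to 0.653 FPKM (2.59-fold lower), as did otx2. Falls were again in excess by Fisher's exact test (adjusted p = 0.00216), with the median at percentile 78.7.

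In the ventral and epidermal ectoderm list, the authors' deposited table called 7 of 27 higher and 3 lower (9 and 4 when adjusted over the list alone). The BMP pathway inhibitor smad7 rose from 23.8 to 36.7 FPKM (1.55-fold), as did id1, and crabp2b (1.46-fold lower), eve1 (1.29-fold lower) and bmp4 (1.27-fold lower) fell. Neither direction was in excess (Fisher's exact test, adjusted p = 0.650 for rises and 0.281 for falls), and the median was -0.083 relative to all genes (percentile 48.8). Over members with a mean of at least 10 FPKM the median turned to 0.14, above the random lists (percentile 98.3). Of 8 endoderm genes, the authors' deposited table called sebox higher (13.4 to 18.1 FPKM, 1.35-fold) and sox17 lower (6.22 to 4.18 FPKM, 1.49-fold lower), and the same counts of 1 and 1 held when adjusted over the list alone. sox32, the endoderm determinant, was not called, at 188 and 187 FPKM. The endoderm list's median lay at percentile 31.3, and its falls had an adjusted p = 0.517 by Fisher's exact test.

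Genes of the enveloping layer, the outer epithelium of the embryo, were lower as a list, and most of the called falls were keratin genes. Of 26 tested, 9 were called lower and 1 higher in the authors' deposited table (9 and 1 when adjusted over the list alone). The keratin gene cyt1l fell from 34.7 to 23.7 FPKM (1.46-fold lower) and the calpain gene capn9 from 71.4 to 50.6 FPKM (1.41-fold lower), while the claudin gene cldn7b, which encodes a tight junction protein, rose from 291 to 407 FPKM (1.4-fold). The other falls were the keratin genes krt4, krt5, krt8, krt17 and krt18, and ppl and anxa1b. Members without a call included cdh1 (296 FPKM in mock, 294 FPKM in Dcp2-DN embryos) and cldnb (166 and 161 FPKM). Falls were in excess by Fisher's exact test (log2 odds 3.60, adjusted p = 8.02e-06). The list's median was -0.33 relative to all genes (percentile 0.03), and it was 0.0071 when ratios were centred on the ribosomal protein genes, which adds the same amount to every gene and leaves the list's place among random lists as it was. With a fold minimum of 1.5 the excess of falls was smaller and did not pass (Fisher's exact test, log2 odds 1.07, adjusted p = 1). For the yolk syncytial layer, the authors' deposited table called 1 of 19 genes higher and 2 lower (1 and 1 when adjusted over the list alone). The regulator mxtx2 rose from 35.8 to 93.6 FPKM (2.62-fold), and the apolipoprotein genes apoa1a (46.7 to 35.3 FPKM, 1.32-fold lower) and apoc1l (339 to 282 FPKM, 1.2-fold lower) fell, with the list's median at percentile 32.9 and an adjusted p = 0.378 for falls (Fisher's exact test).

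**Figure D3:**
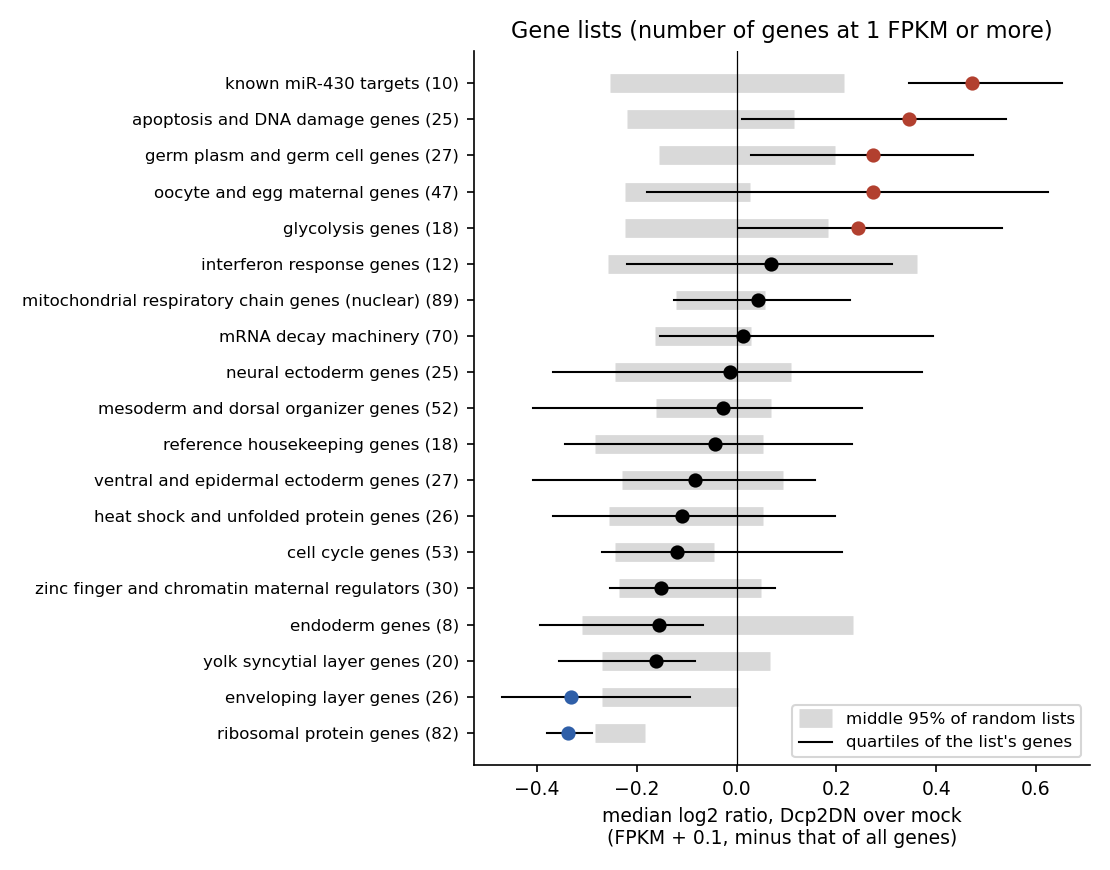
Median log2 ratio of Dcp2-DN over mock for each of the 19 fixed lists, minus the median of all genes (x axis), with the quartiles of the list's genes (lines) and the middle 95% of 10000 random lists matched on expression (grey bars). Red points lie above and blue points below the random lists, from 0.47 for miR-430 targets to -0.34 for ribosomal protein genes; centring on the ribosomal protein genes instead would move every list by the same amount, which takes the enveloping layer median from -0.33 to 0.0071.

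Genes of apoptosis and the DNA damage response were higher in Dcp2-DN embryos, with 11 of 25 called higher and 0 lower in the authors' deposited table (12 and 0 when adjusted over the list alone, and 13 and 0 at an unadjusted p under 0.05). The stress-response gene gadd45aa rose from 14.9 to 42.8 FPKM (2.87-fold) and cdkn1a, the cyclin-dependent kinase inhibitor p21, from 38.3 to 77.2 FPKM (2.01-fold). The median was 0.35 above that of all genes (percentile 100), and rises were in excess by Fisher's exact test (log2 odds 1.62, adjusted p = 0.0319). In the same exact test the excess was of similar size but did not pass with a fold minimum of 1.5 (log2 odds 1.59, adjusted p = 0.112) and without the member shared with another list, btg2 (log2 odds 1.48, adjusted p = 0.0612).

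Heat shock and unfolded protein genes went both ways. Of 27 tested, 6 were called higher and 5 lower in the authors' deposited table (9 and 8 when adjusted over the list alone). The stress transcription factor gene atf3 (4.17 to 9.38 FPKM, 2.25-fold) and creld2, an endoplasmic reticulum stress gene (9.02 to 19.0 FPKM, 2.1-fold), rose. All 5 called lower in the authors' deposited table encode heat shock proteins: hsp70.3 (1.52 to 0.467 FPKM, 3.24-fold lower, locus shared with 4 other genes), hsp70l (1.52 to 0.683 FPKM, 2.22-fold lower), hsp90aa1.2, hsp90ab1 and hspb1. Falls were in excess by Fisher's exact test (log2 odds 2.43, adjusted p = 0.0193), but rested on few calls. The excess did not pass at q under 0.01 (exact test, log2 odds 1.84, adjusted p = 0.819), with a fold minimum of 1.5, where the odds were larger (log2 odds 3.47, adjusted p = 0.112), or against random lists matched on expression (mean 1.78 falls, adjusted p = 0.174). Of 11 interferon response genes, the authors' deposited table called isg15, a ubiquitin-like antiviral gene, higher (57.2 to 88.0 FPKM, 1.54-fold) and 0 lower. For the interferon list these counts were 1 and 0 when adjusted over the list alone and 2 and 1 at an unadjusted p under 0.05, with an adjusted p = 0.650 for the share of rises (Fisher's exact test).

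Among cell cycle genes, 13 of 52 were called higher and 8 lower in the authors' deposited table, and the counts were the same when adjusted over the list alone. The survivin-related gene birc5b rose from 18.9 to 37.3 FPKM (1.97-fold) and the origin recognition gene orc6 from 39.7 to 75.3 FPKM (1.90-fold, locus shared with 4 other genes). The replicative helicase gene mcm6 fell from 45.9 to 33.6 FPKM (1.37-fold lower) and the topoisomerase gene top2a from 118 to 87.5 FPKM (1.35-fold lower). Falls were in excess by Fisher's exact test (log2 odds 2.08, adjusted p = 0.00715), and with a fold minimum of 1.5 this excess was gone (log2 odds 0.083, adjusted p = 1). It did not pass at q under 0.01, at similar odds (exact test, log2 odds 2.18, adjusted p = 0.162), or against random lists matched on expression (mean 3.97 falls, adjusted p = 0.2503).

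Glycolysis genes were mostly higher where called, with 9 of 18 called higher and 1 lower in the authors' deposited table (10 and 1 when adjusted over the list alone). pgk1 rose from 23.5 to 52.4 FPKM (2.23-fold) and ldha from 7.74 to 13.7 FPKM (1.77-fold), and the hexokinase gene hk1 fell from 7.07 to 4.27 FPKM (1.66-fold lower). The median was 0.24 above that of all genes (percentile 99.4), with log2 odds of 1.95 and an adjusted p = 0.0193 for rises by Fisher's exact test. By the same exact test this excess was somewhat smaller and did not pass at q under 0.01 (log2 odds 1.74, adjusted p = 0.101) and with a fold minimum of 1.5 (log2 odds 1.60, adjusted p = 0.228). Nuclear genes of the mitochondrial respiratory chain showed no excess in the authors' deposited table, with 13 of 89 called higher and 2 lower (9 and 1 when adjusted over the list alone). In this list the ATP synthase gene atp5h (24.2 to 46.9 FPKM, 1.94-fold, locus shared with 1 other gene) and the complex I gene ndufb5 (20.6 to 37.7 FPKM, 1.83-fold) rose. The complex I genes ndufa6 (1.51-fold lower) and ndufs6 (1.36-fold lower) fell, and the test of rises gave an adjusted p = 0.377 (Fisher's exact test).

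Ribosomal protein genes were lower as a group. Of 81 tested, 16 were called lower and 0 higher in the authors' deposited table, and at an unadjusted p under 0.05 these Cuffdiff counts were 46 and 0. When adjusted over the list alone, 0 were called in either direction. rps15a went from 193 to 150.4 FPKM (1.28-fold lower), and rplp0 from 363 to 290.3 FPKM (1.25-fold lower, locus shared with 6 other genes). The list's median was -0.34 relative to all genes and -0.22 before centring, below all 10000 random lists (percentile 0). These lists were matched on expression, and most of their medians lay between -0.285 and -0.183, so genes of similar abundance shared part of this shift. The 16 falls stood against a mean of 7.69 in matched lists (permutation, adjusted p = 0.0312). The 0 rises stood against a mean of 7.68 (permutation, adjusted p = 0.00633). Without matching, both the excess of falls (log2 odds 2.499, adjusted p = 6.21e-06) and the lack of rises (adjusted p = 5.48e-07) passed Fisher's exact test. The excess of falls was nearly gone in this exact test at q under 0.01 (log2 odds 0.24, adjusted p = 1) and, with a fold minimum of 1.5, turned direction (log2 odds -0.55, adjusted p = 1).

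The list of chromatin and maternal transcription regulators showed no excess, with 3 of 30 called higher and 2 lower in the authors' deposited table (3 and 1 when adjusted over the list alone; Fisher's exact test, adjusted p = 0.377 for rises). The pluripotency factor genes nanog (388 to 613 FPKM, 1.58-fold) and sox19b (70.21 to 105 FPKM, 1.5-fold) rose, as did brd2b (19.6 to 27.3 FPKM, 1.4-fold). The remodeller gene chd4b (65.0 to 48.7 FPKM, 1.33-fold lower) and the deacetylase gene hdac1 (450.5 to 378 FPKM, 1.19-fold lower) fell. Genes often used as references were not all level. Of 18, the authors' deposited table called hprt1 (1.88-fold), tbp (1.38-fold), rnf11b (1.32-fold) and gapdh (1.28-fold) higher, and ubc (1.21-fold lower) and actb2 (1.21-fold lower) lower. Adjusted over the list alone, 5 were higher and 3 lower, and neither direction was in excess (Fisher's exact test, adjusted p = 0.867 and 0.377). The reference list's median was -0.043 relative to all genes (percentile 85.8) and 0.054 at a mean of at least 10 FPKM, above the random lists (percentile 97.9).

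**Figure D4:**
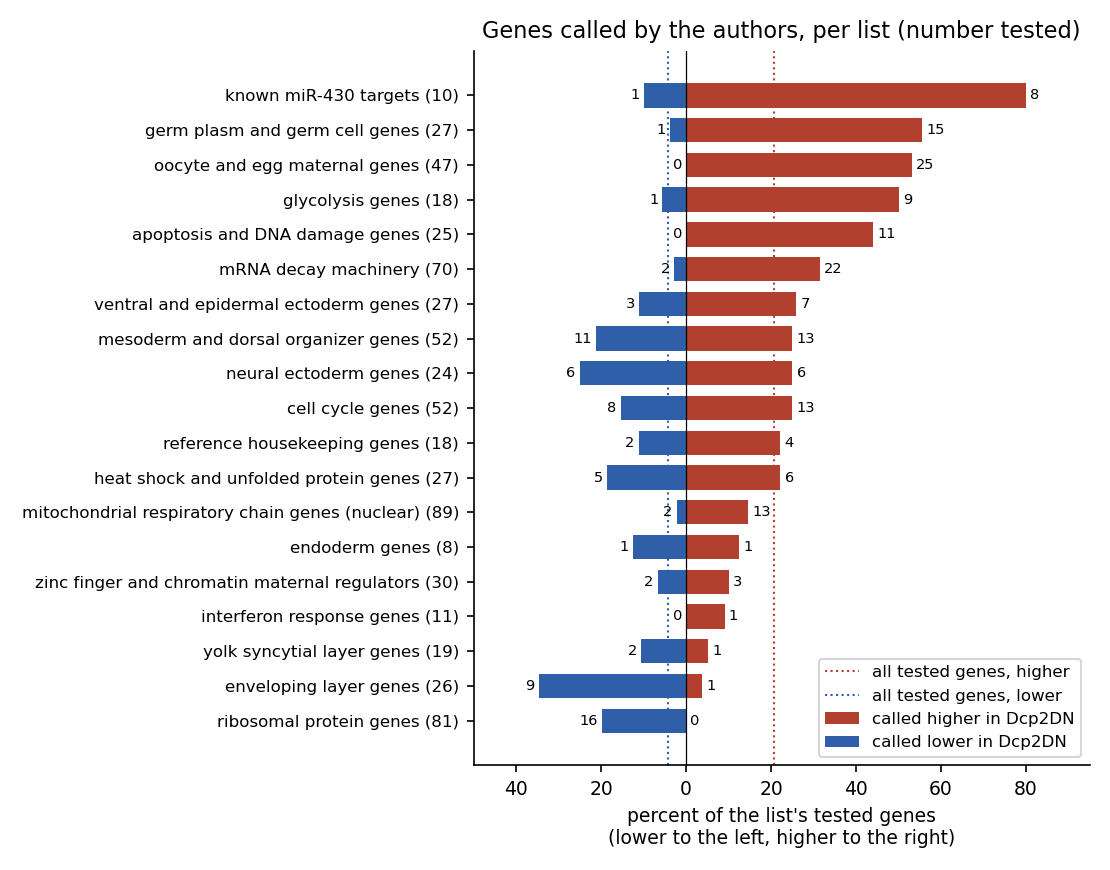
Percent of each list's tested genes called higher (red, right) and lower (blue, left) in the authors' deposited table, with the number of genes at each bar. Dotted lines mark all tested genes (20.6% higher, 4.35% lower); the miR-430 list reaches 8 of 10 higher, and the enveloping layer list 9 of 26 lower.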

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

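The rows below lie outside the authors' test and were looked for only after the table had been seen. Among rows without a test in the authors' deposited table, small structural RNAs recognised by name were left out. Of the rest, 5 reached 10 FPKM in Dcp2-DN embryos and were at least 2-fold above the mock value. A further 4 were as far below it. Of these 5, svila, a gene related to the actin-binding protein supervillin (ENSDARG00000094306, chromosome 12, 25234968 to 25355016), was listed at 1.67 FPKM in mock and 31.1 FPKM in Dcp2-DN embryos, 18.6-fold higher, with the status LOWDATA in the authors' deposited table. The other 4 had clone-based names and were listed at 0 in mock. Among the 4 lower rows, the retinoid receptor gene rxrga (ENSDARG00000095862, chromosome 2, 20495130 to 20546256) was listed at 19.2 FPKM in mock and at 0 in Dcp2-DN embryos, also with the status LOWDATA. Both genes span long loci, and no replicate error can be given for either, so these values do not test a difference between the conditions.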

How the results depend on the processing

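The pseudocount, filter, q threshold, fold minimum and centring were chosen before the data were examined; those named below as added were chosen after the data were seen. Directions held for the 76 named genes other than dcp2 under a pseudocount of 1 and after centring (an added setting). The median log2 ratio of all genes kept its sign under all 5 settings tried. Counts moved with the threshold: 2004 higher and 230 lower at q under 0.01, and 470 and 27 with a 2-fold minimum, in the authors' deposited table. Rows above 1.5-fold numbered 4381 with no filter on low values and 918 at a mean of at least 10 FPKM; rows beyond 1.5-fold lower numbered 1857, 112 and, with a pseudocount of 1, 256. Fewer or more rows pass each filter by construction.

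Of the list medians, ventral ectoderm (0.14) and reference genes (0.054) passed above the random lists at a mean of at least 10 FPKM, and the enveloping layer reversed to 0.0071 when centred on ribosomal protein genes, a step that shifts every gene alike and so cannot move a list among random lists. List calls below are log2 odds with Fisher's exact test, adjusted p in parentheses; without these changes the odds were 2.26 for germ plasm rises, 1.62 for apoptosis rises, 1.95 for glycolysis rises, 3.60 for enveloping layer falls, 2.43 for heat shock falls, 2.08 for cell cycle falls, 2.499 for ribosomal falls and 0.84 for decay gene rises. Stricter settings leave fewer calls by construction, which weakens the test at equal odds; no other cause was tested. At q under 0.01, decay genes passed for rises at 1.28 (0.00988), and heat shock falls at 1.84 (0.819), cell cycle falls at 2.18 (0.162), glycolysis rises at 1.74 (0.101) and ribosomal falls at 0.24 (1) no longer did. With a 1.5-fold minimum, no longer past were germ plasm rises at 1.69 (0.0693), apoptosis rises at 1.59 (0.112), glycolysis rises at 1.60 (0.228), enveloping layer falls at 1.07 (1), heat shock falls at 3.47 (0.112) and cell cycle falls at 0.083 (1), and ribosomal falls reversed to -0.55 (1). In the added settings, apoptosis rises without shared members stood at 1.48 (0.0612). Against matched random lists, heat shock falls were at 1.27 (0.174) and cell cycle falls at 0.93 (0.2503), as log2 of observed over mean calls. For dcp2, the first gene model moved to 0.15 after centring, and the second to 10.45 after centring and 7.68 with a pseudocount of 1.

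No paired analysis was possible because the table holds 1 value per gene and group. For the same reason count-based tools and normalizations, leaving out replicates and a pseudocount per library were not run; transcript features were not run for want of transcript sequences.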

Other observations

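All tests in this part were chosen after the results were seen. Genes were grouped by the stem of their symbol, and 438 tests of calls in the authors' deposited table (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted) were made over the stems with at least 8 tested genes. Each was repeated against random lists matched on expression (permutation, adjusted over the same 438 tests). Keratins stood out among the falls, with 8 of 11 called lower in the authors' deposited table (adjusted p = 7.88e-07, and 0.0438 against matched lists). Examples are krt4, from 917 to 688 FPKM (1.33-fold lower), and krt18, from 1519 to 1237 FPKM (1.23-fold lower). 5 of these 8 keratins also belong to the enveloping layer list, and the 3 others are KRT23 copies, whose reads the authors' counting could split. Genes of the mcm stem, which includes the replication helicase, went both ways in the authors' deposited table, with 5 of 13 called lower and 2 higher (MCM8, 1.32-fold, and mcm3l, 1.39-fold). The falls of the mcm stem exceeded those of other genes (exact test, adjusted p = 0.00806) and of matched lists (adjusted p = 0.0438). These 5 falls were mcm2, mcm4, mcm6 and mcm3, which was counted under separate gene models (ENSDARG00000024204 and ENSDARG00000090802). All 5 also belong to the cell cycle list. Pre-mRNA processing factors (prpf, 5 of 15 called lower) passed the exact test (adjusted p = 0.0155) but not the comparison with matched lists (adjusted p = 0.182).

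Among rises, sorting nexins, which act in endosomal sorting, had 14 of 28 genes called higher in the authors' deposited table (exact test, adjusted p = 0.0202, but 0.274 against matched lists), led by snx10a from 31.9 to 89.9 FPKM (2.81-fold). Genes named only as transmembrane proteins (tmem, 58 of 158) or by sequence family (fam, 57 of 153) held more rises too (exact test, adjusted p = 0.000218 and 0.000187, and 0.0438 for both against matched lists). Protein phosphatase genes (ppp) had 27 of 68 called higher in the authors' deposited table (exact test, adjusted p = 0.0175, and 0.0438 against matched lists). Syntaxins (stx, 8 of 14, exact test, adjusted p = 0.0850) did not pass. By chromosome (50 tests), the authors' deposited table called 13.5% of 740 tested genes on chromosome 4 higher, against 20.6% of all tested genes (exact test, adjusted p = 2.15e-05). Chromosomes 5 (25.3% of 879, adjusted p = 0.0144) and 17 (26.4% of 504, adjusted p = 0.0158) held more rises by the same exact test. Chromosomes 10 (1.64%) and 4 (2.16%) held fewer falls (exact test, adjusted p = 0.0158 for both). The chromosome tests were not repeated against lists matched on expression, so differences in expression level were not separated from position. For rises on chromosome 4, restricted to named genes other than zinc finger and structural RNA genes, which left out 419 rows, the shares were 19.3% of 321 on chromosome 4 and 22.6% elsewhere (Fisher's exact test, p = 0.175).

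The oocyte and egg list was higher and the ribosomal protein list lower. A single scale factor between the groups cannot give both, since the list medians differed by 0.61 (bootstrap interval over genes 0.32 to 0.83). For the ribosomal part, a larger share of reads taken by other transcripts stays open. RNA polymerase III transcripts, which carry no cap that Dcp2 removes, had a median log2 ratio of -0.18, near that of the ribosomal list (-0.22). Its interval over rows (-0.20 to -0.15) is too narrow where rows are copies of the same RNA, which are not independent. Rows with a mean of 500 FPKM or more also had a median of -0.18, and -0.17 without small structural RNAs. Embryos at a younger stage also stay open. Of the 46 called germ layer genes, 43.5% were lower (exact 95% interval 28.9 to 58.9), against 17.4% of all called genes. Falls thus made up a larger share of calls among germ layer genes, though 26 were called higher and 20 lower. The prediction for a younger stage, that most of them would be lower, was neither met nor excluded by this interval. Retention of maternal mRNA through the Dcp2-DN treatment is the explanation the design gives, as a hypothesis that was not tested apart from these.

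Genes of the apoptosis and DNA damage response list were higher. Their expression level does not account for the number of calls, since random lists matched on mean FPKM held 4.85 rises on average against 11 in the authors' deposited table (two-sided permutation p = 0.0096). A general stress of the injected embryos may contribute: rises in the heat shock list did not exceed matched random lists (permutation p = 0.504), but stress need not raise those genes, so it cannot be told apart from an effect of Dcp2-DN. The mock injection need not match the load of the Dcp2-DN injection, which these data do not show.

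The second dcp2 gene model was high in Dcp2-DN embryos. The first model was 2.82 FPKM above mock while the second was 212 FPKM above. Reads moved from the first model would have lowered it, but at 13.9 FPKM in mock it could not fall by as much as the second gained. Reads of the construct may also count for the first model and hide a loss, so a smaller shift of reads cannot be told from these values. Reads of the injected construct are a candidate explanation that stays open. The second model's log2 ratio (10.56) had rank 1 among the rows at a mean of 1 FPKM or more, without small structural RNAs recognised by name. The next in the same set was 9.31, for CU550700.2, a short row without a test. This rank only restates the size of the difference. No read sequences were analysed here, so the source of the reads was not tested.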
